A study of Homo sapiens with 12 samples.

How the data were processed

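BrdU-Seq libraries were made from BJ-hTERT cells, human foreskin fibroblasts immortalised with telomerase, an established cell line. BrdU is a thymidine analogue that replicating cells build into new DNA, and the labels name an anti-BrdU antibody for every library, so the reads come from immunoprecipitated genomic DNA and not from RNA. The 12 libraries form 6 groups of 2: ATMi, ATRi, RAD6i, PARPi, CTR siRNA and PrimPol siRNA. The labels give no dose, treatment time or length of BrdU labelling, and their protocol text describes chromatin immunoprecipitation with other antibodies, so how the BrdU DNA was prepared is not given in the sources used here. Groups were taken from the condition label of each sample. The second PARPi library is labelled PAPRi2 and was read as PARPi replicate 2.

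The deposited values are CPM (reads over the gene scaled to the library total) over whole gene bodies and not divided by gene length. Per the submitters' processing notes, Bowtie2 2.3.3.1 and SAMtools 1.4 were used with the hg38 build; the counting tool, its treatment of strand and any filter on genes are not given in the sources used here. The table lists 12425 genes by Ensembl identifier with chromosome, start, end and length, and 0 rows name no gene. It also holds 2 further columns of per-sample values, named for DMSO, that match no sample label; they can belong to another series and were not used. The listed genes are part of the genome's genes, and genes outside the table were not analysed here.

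Low CPM values stepped by the worth of 1 read, so whole reads were recovered: 100% of the deposited CPM values in every library came out within 0.05 of a whole read. The recovered library totals ran from 11748348 reads in CTR siRNA replicate 1 to 53720608 in RAD6i replicate 2. The value of 1 read ran from 0.0186 to 0.0851 CPM. PCR copies cannot be told from separate molecules in such a table, so depth here bounds counting error only.

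The reference table of gene names gave no Ensembl identifiers, so symbols were given by position on the same build: a gene was named where 1 annotated gene overlapped it reciprocally by at least 0.8 and the next best by under 0.5. In this way 9578 genes received a symbol, 8895 of them protein coding, and 2847 stayed without one but remained in all tests and counts. Gene bodies overlap: 4469 listed genes, 36.0%, share bases with another listed gene, and the DNA signal of such a pair cannot be separated. Of the 131 genes named by the rule, 36 overlap another listed gene, and 3 over more than 0.5 of their length, IFIT1 and IFIT3 among them. Some genes and 1 gene list that were tested are not reported here.

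Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(CPM + 1), with group means over all 12 libraries, 6 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 1) scale, which understates changes of genes with low signal. No filter on low values was applied in this fit, so the fit without a filter, chosen as a variation, is this same fit. A value with its SD is the mean CPM of the 2 libraries of a group. The tests, lists, naming rule and the first set of variations were fixed before the data were examined, for counts as well as for normalized values, and the form for normalized values was the one used. The 2 libraries of a group are not said to come from separate cultures, so p-values measure the spread between these libraries, which may be technical. The fit assumed 1 spread per gene for all 6 groups. Yet the SD of the log2 difference within a pair was 0.13 in ATMi and ATRi, 0.39 in PrimPol siRNA and 0.45 in RAD6i. P-values can therefore be too small for RAD6i and PrimPol siRNA and too large for the closer groups. Library pairs were compared first: counts of each pair differed beyond sampling noise (chi-square per degree of freedom 1.98 to 53.3), so no library counts as a copy of another.

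There were 6 comparisons: PrimPol siRNA against CTR siRNA, ATRi against each of ATMi, RAD6i and PARPi, ATRi against the mean of those 3 inhibitors, and ATRi against CTR siRNA. No vehicle library was analysed here, so each inhibitor is seen only against other inhibitors or against transfected control cells. The named genes of a comparison are the 8 largest rises and 8 largest falls past the threshold, among the upper 75% of genes by mean level, with both libraries of a group above both of the other (for the mean of 3 inhibitors, beyond each group's mean), at most 1 gene per 1 Mb, leaving out symbols of non-coding RNAs, pseudogenes, X-inactivation transcripts and Y-linked genes. Where none passed, the 3 smallest p in each direction were taken. The 2 members of smallest p of each list and the genes of the 7 treatment targets were added. UBE2A, which is among the 7, received no symbol by position and has no value.

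Of 16 gene lists, 12 had the 5 members needed and were tested with camera (preset inter-gene correlation 0.01), adjusted over 72 pairs of list and comparison, again with an estimated correlation, and with fry. The olfactory receptor and immune cell lists had 0 measured members, and the epithelial and keratinocyte list and the melanocyte and endothelial list had 3 each, so these 4 were not tested. The zinc finger list was defined by symbol alone, ZNF with a number, and takes in members such as ZNF609 and ZNF143 that are not KRAB genes.

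The fit was tested on simulated data: counts drawn from these libraries' means and totals with 50 genes changed at each fold. In the simulated comparison of ATRi with ATMi, over 12425 genes, limma found 6% of genes changed 1.25-fold, 26% at 1.5-fold, 52% at 2-fold and 90% at 3-fold, with 4 false calls. In that of PrimPol siRNA with CTR siRNA it found 4%, 26%, 56% and 92%, with 5 false calls. The simulation drew genes independently, with 1 spread per gene for all groups and most genes unchanged. It lacked the common axis between libraries and the unequal spread of the real groups. Its false calls and recovery therefore do not carry over to the real counts.

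The first set of variations was quantile normalization, centring on medians, limma without trend, a stricter filter on low values, pseudocounts of 0.1 and 10, a fit of only the groups compared, the replicate number as a block, correction for gene length, and leaving out each library in turn. Variations chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a library axis as a covariate, the replicate block with the RAD6i numbers crossed, and fits without the libraries or groups whose replicates disagreed. The spread of signal per kb and the classes of genes by signal per kb were also chosen after seeing the data. The library axis is the first component of the residuals from the group means. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. GC content was not examined, since no genome sequence was used here.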

Results

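BrdU signal over gene bodies was measured in 12 libraries of BJ-hTERT fibroblasts, 2 for each of 6 conditions. ATR and ATM are kinases of the DNA damage response, and PARP enzymes bind DNA breaks and modify proteins there. RAD6 is a ubiquitin-conjugating enzyme of damage tolerance, and PrimPol is a primase that restarts DNA synthesis past lesions. The labels ATMi, ATRi, RAD6i and PARPi were read as inhibitors of these proteins, and the series title places ATR inhibition and S-phase transcription at the centre of the study. A gene's value is its share of a library's reads, so it reports labelled DNA recovered over that gene, not its transcription. Libraries held 11748348 to 53720608 reads. The listed genes took 36.7% and 37.1% of the reads in ATRi, the lowest of all groups. They took 41.7% and 41.8% in ATMi, 42.9% and 42.5% in RAD6i and 43.6% and 43.8% in PARPi. CTR siRNA had 40.3% in each library and PrimPol siRNA 38.5% and 39.8%. CPM is scaled to all reads, so this share lowers the summed CPM of listed genes in ATRi. With edgeR, falls against ATMi numbered 1399 on library totals and 576 with its own scaling, which starts from listed reads. Against RAD6i they numbered 2184 and 1687, and against PARPi 2625 and 2097, but 2430 and 2435 against CTR siRNA. Falls called against ATMi thus depend strongly on the scaling. That scaling also evens out other differences between libraries, so the part due to this share alone was not separated.

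The Pearson correlation of log2 values across genes between the 2 libraries of a group was 0.9979 in ATMi, 0.9976 in ATRi, 0.9969 in PARPi and 0.9946 in CTR siRNA, but 0.9829 in PrimPol siRNA and 0.9782 in RAD6i. These are correlations across genes, which are not independent replicates. RAD6i replicate 2 lay closest to PARPi replicate 1 (0.9964) and RAD6i replicate 1 closest to ATMi replicate 1 (0.9907). Both PrimPol siRNA libraries lay closest to CTR siRNA replicate 2 (0.9941 and 0.9882). PrimPol siRNA replicate 2 lay almost as close to the ATMi libraries (0.9875 and 0.9877). It was also nearer to the ATRi libraries (0.985 and 0.9838) than to its own partner (0.9829) or CTR siRNA replicate 1 (0.9824). One axis held 75.8% of the variance within groups, with RAD6i at 33.2 and -19.9 and PrimPol siRNA at -34.9 and 11.6, while ATMi (20.8 and 20.4) and ATRi (15.1 and 17.4) stayed together. The share of listed reads on chromosome 19, which is rich in genes, was 2.84% in RAD6i replicate 1 and 1.80% in RAD6i replicate 2.

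**Figure D1:**
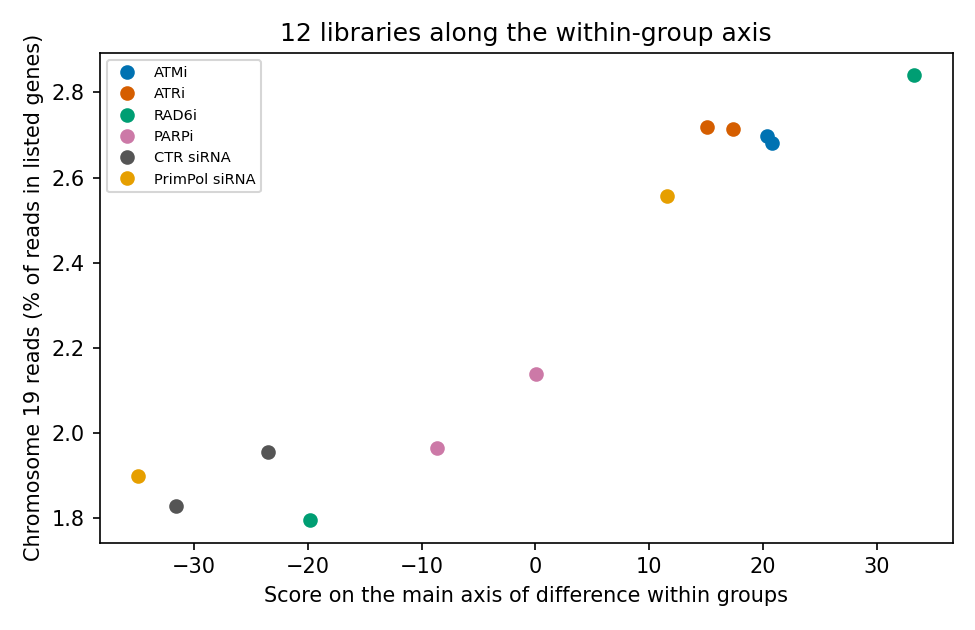
Each point is 1 library, coloured by group; the x axis is its score on the main axis of difference within groups (no unit) and the y axis the percent of listed reads on chromosome 19. The RAD6i libraries sit at 33.2 and -19.9 and the PrimPol siRNA libraries at -34.9 and 11.6, while the ATMi libraries sit at 20.8 and 20.4.

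The genes of the treatment targets were read first. PRIMPOL (ENSG00000164306; hg38 chromosome 4, 184649613 to 184694963) had 9.93 ± 0.0223 CPM (SD, n = 2) in PrimPol siRNA and 10.3 ± 0.727 (SD, n = 2) in CTR siRNA, a log2 fold change of -0.05 (SE 0.143; limma adjusted p = 0.901). An siRNA acts on the transcript and leaves the gene's DNA in place, so this value does not check the knockdown, and the same holds for the inhibitor targets. ATR had 35.5 ± 0.642 CPM in ATRi and 42.5 ± 1.45 in ATMi (SD, n = 2 each), and ATM 29.1 ± 0.794 and 35.1 ± 0.849. Neither passed limma in that comparison (adjusted p = 0.354 and 0.247). UBE2B, which encodes one of the RAD6 proteins, fell in ATRi against RAD6i, from 22.1 ± 0.736 to 15.2 ± 0.431 CPM (SD, n = 2 each; limma adjusted p = 0.0101), and also against PARPi, from 23.1 ± 2.21 CPM (SD, n = 2; limma adjusted p = 0.00448). Against PARPi, PARP1 (limma adjusted p = 0.0407), PARP2 (adjusted p = 0.0329) and PRIMPOL (adjusted p = 0.0314) rose in ATRi, and against RAD6i PARP2 (adjusted p = 0.0254) and PRIMPOL (adjusted p = 0.0158) did.

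PrimPol siRNA against its matched control is the only one of the 6 comparisons with a control named for it in the labels. Among the genes with the smallest p, on the higher side stood TMEM178B (ENSG00000261115; chromosome 7, 141074232 to 141480380), at 65.8 ± 0.537 against 46.2 ± 1.43 CPM (SD, n = 2 each), and MGAT5, a glycosyltransferase, at 88.2 ± 5.54 against 63.2 ± 3.71. On the lower side stood RGS20 at 54.0 ± 0.592 against 69.7 ± 4.95, FAM81A at 91.9 ± 3.04 against 112.0 ± 2.02, and NSD1, a histone methyltransferase, at 109.5 ± 0.822 against 133.0 ± 1.03. Each of these 5 had a limma adjusted p of 0.31, and 0 of 12425 genes passed the threshold. limma gave 1485 genes at an unadjusted p under 0.05, while edgeR and DESeq2 on recovered reads also called 0 genes. With the library axis as a covariate limma called 1710, and with RAD6i replicate 2 and PrimPol siRNA replicate 2 both left out 1647; these 2 settings were chosen after seeing the data.

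Among the fixed lists in this comparison, common fragile site genes included WWOX (log2 fold change 0.50, SE 0.085) and DAB1 (0.21, SE 0.05), very long genes that break under replication stress; 5 of the 18 members passed when adjusted over the list alone, all higher, and 0 over all genes. The list as a whole had a median log2 of 0.016, with library pairs from -0.038 to 0.125, and camera did not call it (adjusted p = 0.157, and adjusted p = 0.919 with an estimated correlation), though it did after quantile normalization (adjusted p = 2.31e-06). RAD50, of the break-sensing MRN complex, stood at -0.31 (SE 0.075) and the helicase BLM at -0.22 (SE 0.058). Camera placed the damage response list lower (adjusted p = 0.0319), the 264 zinc finger genes higher (median log2 0.15; adjusted p = 0.00115) and the 12 mitochondrially encoded genes lower (mean log2 -0.34; adjusted p = 0.00694). With an estimated correlation these became adjusted p = 0.919 each. The mitochondrial median ran from -1.02 to 0.30 over the 4 library pairs, and without CTR siRNA replicate 1, the shallowest library, the direction turned (adjusted p = 0.624). Without PrimPol siRNA replicate 2 the mitochondrial call ended (adjusted p = 0.905) and the damage response list turned direction (adjusted p = 0.96). The damage response call also ended without CTR siRNA replicate 2 (adjusted p = 0.105) and after quantile normalization (adjusted p = 0.176), and the zinc finger call without PrimPol siRNA replicate 1 (adjusted p = 0.457) and after quantile normalization (adjusted p = 0.358). With the library axis as a covariate the damage response (adjusted p = 0.695) and mitochondrial (adjusted p = 0.0671) calls ended, while camera called the fragile site (adjusted p = 8.97e-07) and synaptic (adjusted p = 0.00569) lists. Chromosome 19 genes had a median of 0.20, with pairs from -0.08 to 0.47.

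ATRi against ATMi sets the kinase in the series title against its relative, and these 2 groups held the closest replicates. PELI2, a ubiquitin ligase of innate signalling (ENSG00000139946; chromosome 14, 56117814 to 56301526), rose from 16.1 ± 0.14 to 35.3 ± 0.167 CPM (SD, n = 2 each; log2 1.09, limma adjusted p = 0.000426). TMTC1 (ENSG00000133687; chromosome 12, 29500840 to 29784759) rose from 63.0 ± 0.787 to 130.8 ± 4.25 CPM (log2 1.04, adjusted p = 0.000346), and the transcriptional corepressor TLE1 from 16.4 ± 0.0706 to 33.4 ± 0.454. PSMA1, a proteasome subunit (ENSG00000129084; chromosome 11, 14504874 to 14643635), fell from 146.3 ± 4.58 to 74.7 ± 2.82 CPM (log2 -0.96, adjusted p = 0.000346), and SNX14 from 87.1 ± 1.77 to 46.6 ± 0.0745.

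TRIML2 (1.08), EDA2R (0.93), PITPNM3 (0.93), LURAP1L (0.92) and TRIM45 (0.89) were the other large rises in log2 fold change against ATMi, with limma adjusted p from 0.00362 to 0.0186. SLC25A36 (-0.93), ZNF333 (-0.92), APRG1 (-0.91), RARS2 (-0.91), RTCB (-0.91) and SEPTIN2 (-0.90) were the other large falls. limma called 1786 of 12425 genes, 391 higher and 1395 lower, and the median over all genes was -0.08. Counts were 479 without ATMi replicate 1, 426 without ATMi replicate 2, 414 without ATRi replicate 1 and 518 without ATRi replicate 2, but 6243 in a fit of only these 4 libraries (1924 higher, 4319 lower). Normalization mattered too: 1100 genes passed after quantile normalization (541 higher, 559 lower) and 490 after centring on medians, while 829 passed with edgeR on recovered reads.

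Of 41 DNA replication and fork genes, 1 rose, 8 fell and 32 did not pass; 9 passed when adjusted over the list alone. ORC2, of the origin recognition complex (ENSG00000115942; chromosome 2, 200908973 to 200963680), fell from 45.2 ± 0.778 to 26.0 ± 0.135 CPM (SD, n = 2 each), and WDHD1, a replisome factor, from 79.8 ± 1.77 to 49.6 ± 1.77. Of 33 damage response and gap repair genes 0 rose and 6 fell, among them FANCD2 (log2 -0.53) and BRCA1 (-0.53); 9 passed adjusted over the list alone. BRCA1 shares 39.7% of its length with other listed genes. Of 18 common fragile site genes 3 rose and 5 fell, LPP by 0.54 and PARD3B by 0.48 on the log2 scale, and 8 passed adjusted over the list alone. Of 30 fibroblast matrix genes 0 rose and 4 fell, among them FBN1 (-0.53) and CALD1 (-0.51), with 4 adjusted over the list alone. Of all genes 14.4% passed limma against ATMi, 391 higher and 1395 lower, so falls outnumbered rises outside these lists too.

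The other lists reported here held few calls against ATMi. Of 19 interferon-stimulated genes 1 rose and 2 fell, HERC6 (-0.40) and USP18 (-0.64), with 3 adjusted over the list alone. Of 63 ribosomal protein genes 0 rose and 2 fell, RPS27A (-0.58) and RPS24 (-0.64), with 0 adjusted over the list alone. The zinc finger list had 9 rises and 19 falls of 264, including ZNF678 (-0.85) and ZNF609 (-0.53), with 17 adjusted over the list alone. No member passed among 20 immediate early, 15 replication-dependent histone, 12 mitochondrially encoded and 7 synaptic and neuronal genes, and 0 passed in each adjusted over the list alone. Camera called none of the 12 lists here.

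In ATRi against RAD6i, COL4A6, a basement membrane collagen (ENSG00000197565; chromosome X, 108155607 to 108439497), rose from 11.9 ± 0.97 to 38.0 ± 0.746 CPM (SD, n = 2 each; log2 1.59, limma adjusted p = 0.000104). NFATC1, a calcium-responsive transcription factor, rose by a log2 of 1.54, TMTC1 by 1.44 and PMEPA1 by 1.43. SMC4, a condensin subunit (ENSG00000113810; chromosome 3, 160399274 to 160434962), fell from 22.2 ± 5.85 to 9.01 ± 1.01 CPM (log2 -1.19, adjusted p = 0.001), and HERC4, a ubiquitin ligase, from 180.2 ± 32.9 to 90.0 ± 0.34. TSC22D2 (-1.01), NUDT12 (-0.995), ST13 (-0.97), ARHGAP11A (-0.96), KMT2E (-0.96) and MBNL1 (-0.96) were the other large falls in log2 fold change, and STX2 (1.404), PPP2R2D (1.39), CD82 (1.38) and LPCAT1 (1.36) the other large rises.

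Camera placed the zinc finger genes higher against RAD6i: 76 of 264 rose, 14 fell and 174 did not pass, with 98 adjusted over the list alone (median log2 0.33; camera adjusted p = 1.27e-06; adjusted p = 0.814 with an estimated correlation). Its members of smallest p, ZNF143 (-0.64) and ZNF609 (-0.44), fell. Chromosome 19 genes had a median of 0.16, with library pairs from -0.18 to 0.51. Of 30 fibroblast matrix genes 8 fell and 0 rose, with 9 adjusted over the list alone, FBN1 by 0.75 and CALD1 by 0.61 on the log2 scale (camera adjusted p = 0.0319; adjusted p = 0.919 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.0742) and without RAD6i replicate 1 (adjusted p = 0.107). Of 33 damage response genes 12 fell and 2 rose, with 16 adjusted over the list alone, FANCD2 at -0.66. Of 41 replication genes 8 fell and 6 rose, with 14 adjusted over the list alone, ORC2 at -0.86 and WDHD1 at -0.83. Camera called neither the damage response (adjusted p = 0.187) nor the replication list (adjusted p = 0.697), and 27.2% of all genes passed limma. Among the 18 fragile site genes 4 rose and 4 fell, with 8 adjusted over the list alone, WWOX at 0.71 and LPP at -0.47. Camera did not call that list (adjusted p = 0.511), but did after quantile normalization (adjusted p = 7.56e-06). SPATA18, a mitochondrial quality control gene, rose by 1.21.

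limma called 3380 genes against RAD6i, 1266 higher and 2114 lower. The RAD6i libraries differ from each other more than any other pair: in a fit of only these 4 libraries 0 genes passed. The counts were 1611 without ATRi replicate 1 and 1804 without ATRi replicate 2. Quantile normalization left 2238.

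In ATRi against PARPi, PMEPA1, a negative regulator of TGF-beta signalling (ENSG00000124225; chromosome 20, 57648392 to 57711536), rose from 2.04 ± 0.648 to 9.50 ± 0.753 CPM (SD, n = 2 each; log2 1.80, limma adjusted p = 0.000922), COL4A6 from 11.4 ± 0.638 to 38.0 ± 0.746 (log2 1.65, adjusted p = 2.65e-05), and TMTC1 from 44.0 ± 3.3 to 130.8 ± 4.25. LPCAT1 (1.66), NFATC1 (1.63), PRDM2 (1.57), GFPT2 (1.54) and SHANK1 (1.53) rose as well. SMC4 fell from 26.2 ± 0.886 to 9.01 ± 1.01 CPM (log2 -1.44, adjusted p = 0.00022) and SMARCAD1, a chromatin remodeller, from 76.5 ± 4.14 to 29.4 ± 1.05. ATG3 (-1.36), ST13 (-1.34), FAM76B (-1.34), SNX14 (-1.32), CPSF6 (-1.31) and mitochondrial ND3 (-1.30) also fell.

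The fragile site gene PDE4D (ENSG00000113448; chromosome 5, 58969038 to 60522120) rose from 135.1 ± 4.28 to 282.6 ± 3.95 CPM against PARPi while LPP fell by 0.63 on the log2 scale; 4 of the 18 rose and 6 fell, with 10 adjusted over the list alone. Quantile normalization turned the direction of that list's test (adjusted p = 0.00394). Of 41 replication genes 11 fell and 4 rose, with 15 adjusted over the list alone, ORC2 at -1.15 and WDHD1 at -1.08. Of 33 damage response genes 13 fell and 4 rose, with 19 adjusted over the list alone, RAD50 at -0.67. Of 30 matrix genes 10 fell and 0 rose, with 10 adjusted over the list alone, FBN1 at -0.85. On CPM as deposited camera called none of these lists. Its adjusted p was 0.95 for fragile site, 0.697 for replication, 0.0515 for damage response and 0.157 for matrix genes. Of all genes 33.2% passed limma. Zinc finger genes were higher by camera (77 rose, 27 fell, 112 adjusted over the list alone; adjusted p = 0.000179, and adjusted p = 0.814 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.214). Mitochondrially encoded genes were lower (0 rose, 4 fell of 12, 6 adjusted over the list alone; adjusted p = 0.0257, and adjusted p = 0.919 with an estimated correlation), and not called without PARPi replicate 2 (adjusted p = 0.0879) or with the library axis as a covariate (adjusted p = 0.144). NLGN1, a synaptic adhesion gene, fell by 0.40 (adjusted p = 0.0486), a call lost with its sign after quantile normalization (0.01, adjusted p = 0.956).

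limma called 4122 genes against PARPi, 1500 higher and 2622 lower. Counts were 2529 without ATRi replicate 1, 2656 without ATRi replicate 2, 2629 without PARPi replicate 1 and 2663 without PARPi replicate 2. In a fit of only these 4 libraries 7497 passed, 3807 higher and 3690 lower, and without the RAD6i and PrimPol siRNA groups 7260, 3635 higher and 3625 lower, so the excess of falls depends on the libraries in the fit.

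Against the mean of the other 3 inhibitors, PMEPA1 (log2 1.39), NFATC1 (1.35), TMTC1 (1.35), LPCAT1 (1.30), PELI2 (1.29), CD82 (1.27), TRIML2 (1.23) and SHANK1 (1.21) rose in ATRi. ATG3 (-1.05), SMC4 (-1.05), SNX14 (-1.04), FAM76B (-1.03), the mitotic kinesin KIF18A (-1.02), SMARCAD1 (-1.01) and NEXN (-0.99) fell, with limma adjusted p from 3.56e-05 to 0.00131. ORC2 had 26.0 ± 0.135 CPM (SD, n = 2) in ATRi against 50.9 ± 6.98 in the 6 libraries of the other inhibitors, and WDHD1 49.6 ± 1.77 against 91.5 ± 11.9. Of all genes 31.8% passed limma here. Zinc finger genes were higher by camera (74 rose, 26 fell of 264, 107 adjusted over the list alone; adjusted p = 0.000163, and adjusted p = 0.814 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.182). limma called 3953 genes, 1428 higher and 2525 lower, with 2001 without ATRi replicate 1 and 2182 without ATRi replicate 2.

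ATRi against CTR siRNA is not a matched comparison, since the control cells received an siRNA and the labels name none for the inhibitor cells. CD82, a tetraspanin (ENSG00000085117; chromosome 11, 44564427 to 44620363), rose from 4.63 ± 0.772 to 15.97 ± 1.64 CPM (SD, n = 2 each; log2 1.60, limma adjusted p = 0.00566), with AGRN (1.52), ULK1 (1.45), MEGF6 (1.43), ADGRB2 (1.43), NEURL4 (1.41), AMOTL2 (1.39) and SEMA7A (1.39). PAPOLA, a poly(A) polymerase (ENSG00000090060; chromosome 14, 96501433 to 96567111), fell from 23.0 ± 2.88 to 6.30 ± 0.323 CPM (log2 -1.71, adjusted p = 0.000229), and FUT8, a fucosyltransferase, from 230.6 ± 14.9 to 85.7 ± 1.55. SLC25A36 (-1.68), CPSF6 (-1.53), FAM76B (-1.53), NUS1 (-1.49) and SHOC2 (-1.39) fell too.

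Of 33 damage response genes 18 fell and 1 rose against CTR siRNA, with 21 adjusted over the list alone, the translesion polymerase subunit REV3L by 1.20 and MRE11 by 0.79 on the log2 scale (camera adjusted p = 0.000706; adjusted p = 0.919 with an estimated correlation). ATR (-0.72) and ATM (-0.64) were among the falls. Of all genes 33.8% passed limma in this comparison. Of 18 fragile site genes 7 fell, TMEM135 by 1.05, and 3 rose, with 13 adjusted over the list alone (adjusted p = 0.0414; adjusted p = 0.919 with an estimated correlation). Of 20 immediate early genes 4 rose and 0 fell, with 2 adjusted over the list alone, EGR1 by 0.94 and CCN1 by 0.83 (adjusted p = 0.0244; adjusted p = 0.919 with an estimated correlation). Of 12 mitochondrially encoded genes 6 fell, with 9 adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.919 with an estimated correlation), and 4 of the 7 synaptic and neuronal genes fell, with 4 adjusted over the list alone (adjusted p = 0.0414; adjusted p = 0.919 with an estimated correlation). After quantile normalization the fragile site (adjusted p = 0.258), immediate early (0.21) and synaptic (0.266) calls ended. Without CTR siRNA replicate 1 the mitochondrial (adjusted p = 0.168) and synaptic (0.0532) calls ended, without CTR siRNA replicate 2 the fragile site (0.0526) and synaptic (0.0526) calls, and without ATRi replicate 2 the synaptic call (0.056). With the library axis as a covariate each of these 5 calls ended: damage response (adjusted p = 0.0794), fragile site (0.61), immediate early (0.158), mitochondrial (0.0733) and synaptic (0.499). limma called 4198 genes, 1686 higher and 2512 lower; counts were 1701 without ATRi replicate 1, 1619 without ATRi replicate 2, 1579 without CTR siRNA replicate 1 and 2501 without CTR siRNA replicate 2. In a fit of only these 4 libraries 7830 passed, 4443 higher and 3387 lower, and without the RAD6i and PrimPol siRNA groups 8272, 4729 higher and 3543 lower, so which direction holds more genes depends on the libraries in the fit. Across genes the fold changes correlated at 0.78 with the library axis, against -0.04 for ATRi against ATMi, and chromosome 19 genes had a median of 0.40.

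Genes were also grouped by BrdU signal per kb, a grouping chosen after seeing the data. Classes were set on genes over 10 kb from libraries outside each comparison, and their medians describe genes, which are not independent replicates. Against ATMi the class of lowest signal had a median log2 of 0.17 (186 rose, 27 fell of 1891) and the class of highest signal -0.28 (9 rose, 755 fell of 1890). Against RAD6i these medians were 0.52 and -0.45, and against PARPi 0.57 and -0.52. Against PARPi 882 genes rose and 16 fell in the lowest class, and 1 rose and 1422 fell in the highest. Calls of named genes and lists against the inhibitors were not corrected for signal class. Changes particular to a gene or list were therefore not separated from this broad pattern. Against CTR siRNA they were -0.06 and 0.01. PrimPol siRNA against CTR siRNA had 0.21 and -0.10, with 0 genes past the threshold.

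**Figure D2:**
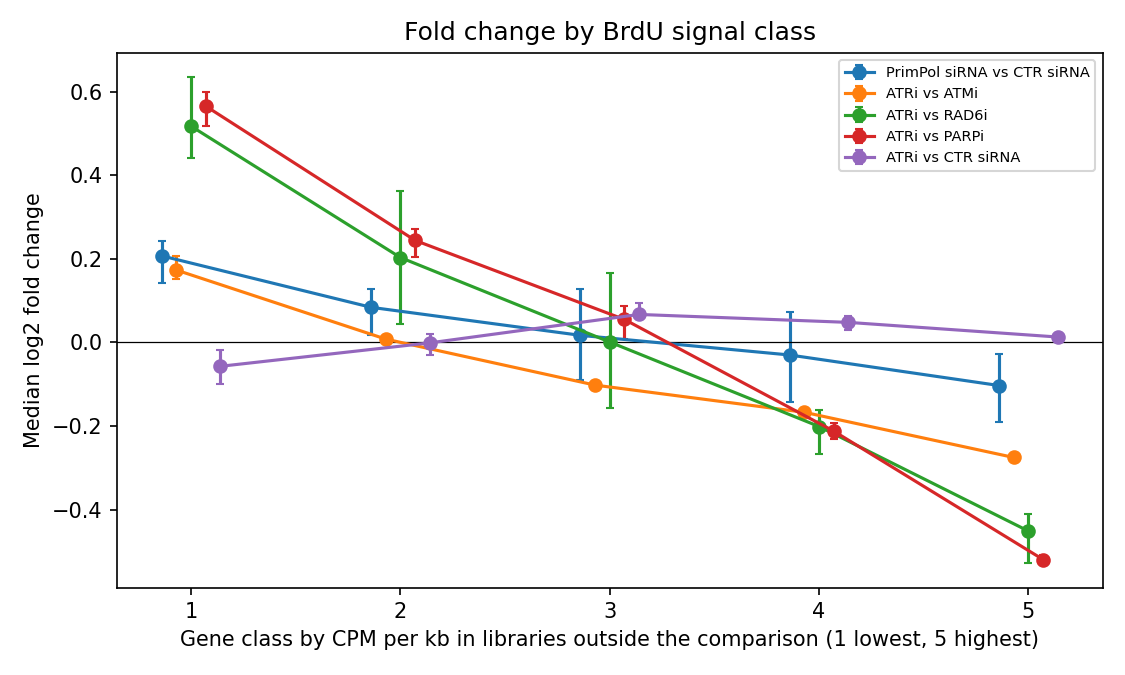
Points are the median log2 fold change (y axis) of the genes in each of 5 classes of BrdU signal per kb (x axis, 1 lowest to 5 highest), for 5 comparisons; bars span the medians of single library pairs. In the comparison of ATRi with PARPi the medians run from 0.57 in class 1 to -0.52 in class 5.

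The interquartile range of log2 CPM per kb over these genes was 1.35 ± 0.015 (SD, n = 2) in ATRi, 1.53 ± 0.0071 in ATMi, 1.77 ± 0.014 in PARPi and 1.84 ± 0.001 in RAD6i. It was 1.33 ± 0.041 in CTR siRNA and 1.13 ± 0.06 in PrimPol siRNA. The 2 libraries of each group lay apart from those of ATMi, PARPi and RAD6i by more than their own spread. With 2 libraries against 2 an exact two-sided permutation test cannot go below p = 0.333.

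**Figure D3:**
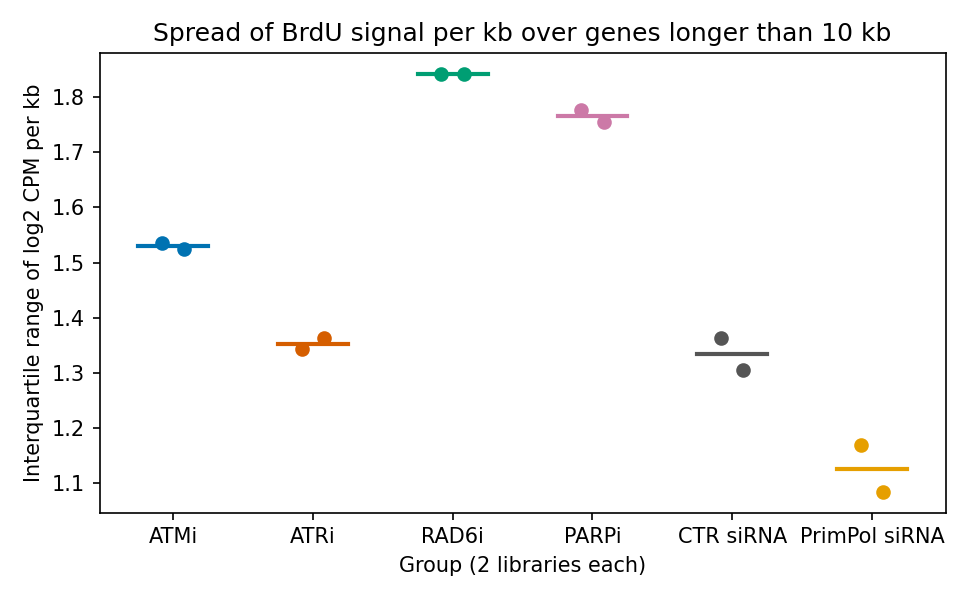
Each point is 1 library and each bar the mean of its group; the y axis is the interquartile range of log2 CPM per kb over genes longer than 10 kb. ATRi lies at 1.35 and RAD6i at 1.84.

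The trend with gene length turned direction with quantile normalization in every comparison but that with CTR siRNA. On CPM as deposited, against ATMi, genes of 100 to 300 kb had a median log2 of -0.22, with 597 falls and 93 rises among 1893 genes, and genes under 10 kb a median of -0.04. Genes over 300 kb stood at -0.16 against ATMi. Against PARPi the 100 to 300 kb class stood at -0.22 and genes over 300 kb at -0.12. Against CTR siRNA these classes stood at -0.295 and -0.32. Spearman's rho of fold change with length across genes was -0.17 against ATMi, -0.16 against RAD6i, -0.23 against PARPi, -0.21 against the mean of the 3 inhibitors and -0.40 against CTR siRNA, and -0.25 for PrimPol siRNA. After quantile normalization rho turned to 0.11, 0.27, 0.17 and 0.20 in the first 4 and 0.13 for PrimPol siRNA, and was -0.12 against CTR siRNA. Without RAD6i replicate 2 rho against RAD6i was 0.03, and without PrimPol siRNA replicate 2 that of PrimPol siRNA was 0.04.

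**Figure D4:**
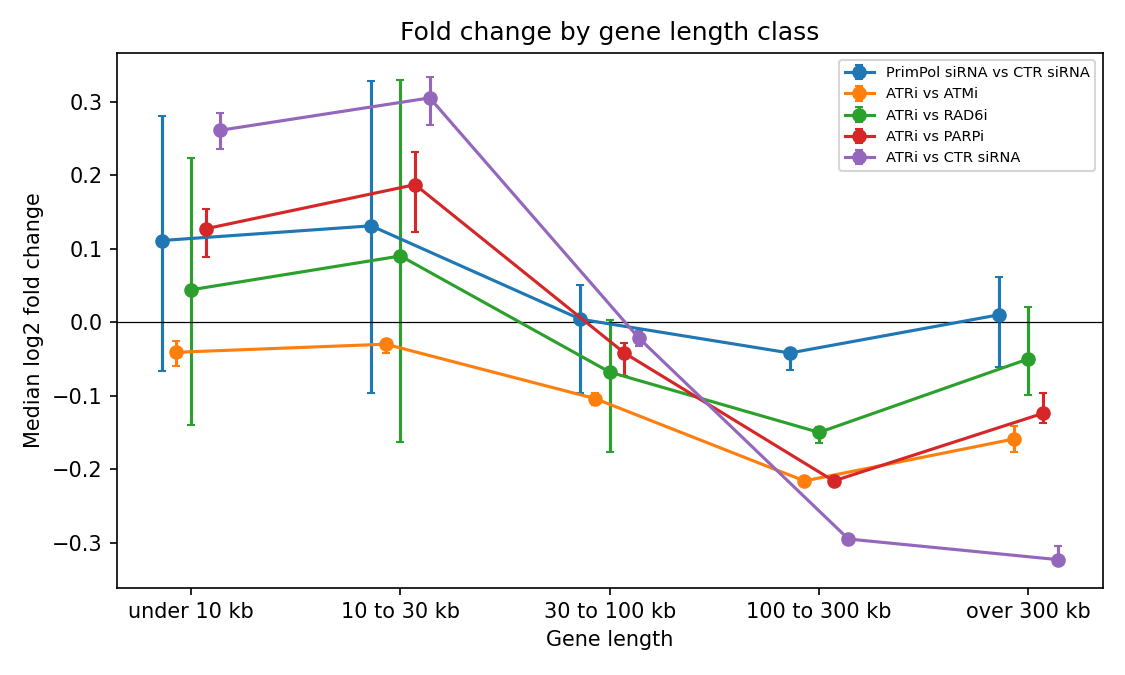
Points are the median log2 fold change (y axis) of genes in each length class (x axis, in kb) for 5 comparisons on CPM as deposited; bars span the medians of single library pairs. Genes of 100 to 300 kb lie at -0.22 for ATRi against ATMi, a direction that the trend over all lengths does not keep after quantile normalization.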

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

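The edgeR, DESeq2, library axis, signal spread, crossed RAD6i numbers and left-out pair or group settings were chosen after seeing the data; the rest were planned. With only the groups compared, the share called higher went from 36.4% to 50.8% against PARPi and from 40.2% to 56.7% against CTR siRNA, so the balance of rises and falls turned. That fit keeps the group means and so every fold change, so no sign could change there. After quantile normalization the fold change of genes called in the main analysis had the opposite sign for 30 against ATMi and 101 against RAD6i. It did for 177 against PARPi, 165 against the mean and 43 against CTR siRNA, and after length correction for 69 against CTR siRNA. Of 183 calls for named genes, 8 were lost with DESeq2, 16 after centring on medians, 13 after quantile normalization, 38 in fits of only the groups compared, 42 without ATRi replicate 1 and 50 without ATRi replicate 2; among these named genes NLGN1 against PARPi alone turned (0.011 after quantile normalization). When a library is left out, its lone partner is assumed to vary like the other groups. Fewer libraries leave fewer degrees of freedom, and the axis, taken from these same residuals, shrinks the residual spread by construction. Fits without groups outside a comparison kept its fold changes. Their higher counts, such as 6243 and 4956 against ATMi, thus come from a smaller residual spread. Against ATMi edgeR called 829 genes with its own scaling of libraries and 1770 with library totals only, so that scaling lowered its count. For each other changed result the cause was not tested.

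Against ATMi (1786 genes) counts were 1100 after quantile normalization, 490 after centring on medians, 6243 with only the groups compared, 1114 after length correction, 829 with edgeR, 1052 with DESeq2, 5038 with the axis, 4956 without the RAD6i and PrimPol siRNA groups and 4959 without RAD6i 2 and PrimPol siRNA 2. The higher share moved from 21.9% to 49.2% with quantile normalization and to 34.0% with DESeq2. Against RAD6i (3380) they were 2238 after quantile normalization, 0 with only the groups compared, 6306 with the axis and 6015 without those 2 libraries. Against PARPi (4122) they were 7497 with only the groups compared, 6489 with the axis, 7260 without the 2 groups and 7260 without the 2 libraries. Against the mean of 3 inhibitors (3953) they were 6777 with the axis and 6437 without the 2 libraries. Against CTR siRNA (4198) they were 7830 with only the groups compared, 8272 without the 2 groups and 8272 without the 2 libraries. For PrimPol siRNA (0) they were 1710 with the axis and 1647 without the 2 libraries. Leaving out each library gave 414 to 518 against ATMi, 1611 to 4189 against RAD6i, 2529 to 2663 against PARPi, 2001 to 4824 against the mean and 1579 to 2501 against CTR siRNA, and 0 for PrimPol siRNA.

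The replicate numbers did not pair the libraries in 1 direction (correlations of deviations from -0.839 to 0.343). RAD6i ran opposite to PrimPol siRNA (-0.839), PARPi (-0.382), CTR siRNA (-0.244) and ATRi (-0.136). PrimPol siRNA went with PARPi (0.343), CTR siRNA (0.214) and ATRi (0.139). ATMi went with no group (-0.025 to 0.015). Whether libraries were paired otherwise than by number cannot be told. With replicate number as a replicate block the counts were 0 for PrimPol siRNA, 1376 against ATMi, 2942 against RAD6i, 3683 against PARPi, 3587 against the mean and 3241 against CTR siRNA. With the RAD6i numbers crossed, 3767 passed against RAD6i and 4346 against the mean.

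Camera called 13 of 72 pairs of list and comparison, 0 with an estimated correlation and 8 with the axis, and 12 to 16 with a library left out. Comparisons called per list, with an estimated correlation, were 0 for fragile site (1), damage response (2), matrix (1), immediate early (1), zinc finger (4), mitochondrial (3) and synaptic genes (1). The fry test passed zinc finger genes against RAD6i and PARPi and damage response genes against CTR siRNA (fry adjusted p = 0.0292 each), and no other pair. After quantile normalization the comparisons called by camera were 4 for fragile site, 1 for damage response, 0 for immediate early, 2 for zinc finger and 0 for synaptic genes. All 4 fragile site calls were new: PrimPol siRNA, RAD6i, PARPi and the mean (camera adjusted p = 0.00272). The call against CTR siRNA ended. Zinc finger genes kept RAD6i, where they were higher, and gained CTR siRNA, where they were lower (camera adjusted p = 0.00393). Matrix genes lost RAD6i, where they were lower, and gained CTR siRNA, where they were higher. With the axis they were 0 for damage response, 2 for matrix, 0 for immediate early and 0 for mitochondrial genes; fragile site and synaptic genes kept 1 each, but in PrimPol siRNA and no longer against CTR siRNA. With a library left out they were 0 to 2 for fragile site, 0 to 1 for ribosomal protein, 1 to 5 for damage response, 0 to 3 for matrix, 2 to 5 for mitochondrial and 0 to 1 for synaptic genes. Directions turned for fragile site genes against PARPi after quantile normalization, where camera gave 0.000273. They also turned in PrimPol siRNA for mitochondrial genes without CTR siRNA replicate 1 and damage response genes without PrimPol siRNA replicate 2. There camera gave p-values of 0.355 and 0.947; over the libraries left out it ran from 1.23e-12 to 0.766 and from 2.72e-05 to 0.947.

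Length rho turned after quantile normalization to 0.13 (PrimPol siRNA), 0.107 (ATMi), 0.271 (RAD6i), 0.172 (PARPi) and 0.203 (mean), and moved to -0.119 (CTR siRNA). With a library left out it ran from -0.352 to 0.039, -0.173 to -0.152, -0.269 to 0.026 and, against CTR siRNA, -0.396 to -0.382. The gap in signal spread against ATMi (-0.177) was -0.131 as an SD. It was -0.462 over genes over 30 kb and -0.343 as an SD against RAD6i (-0.489), -0.327 as an SD against PARPi (-0.412) and -0.267 as an SD against the mean (-0.359). Against CTR siRNA (0.019) it was 0.116 over genes over 30 kb and -0.01 to 0.048 with a library left out.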

Other observations

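The tests of the main axis, of even background and of a mislabelled library were chosen after the results they bear on were seen, as were the measure of signal spread, edgeR and DESeq2 on recovered reads and the library axis as a covariate; the tests of depth and gene length were written down before theirs.

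Against CTR siRNA, 10 of 30 fibroblast matrix genes rose in ATRi and 3 fell, with 20 adjusted over the list alone (16 higher). TPM1, a tropomyosin of the contractile cytoskeleton, rose from 29.3 ± 2.85 to 43.2 ± 0.549 CPM (SD, n = 2 each; limma adjusted p = 0.00419), while FBN1, the microfibril gene, fell from 285.5 ± 7.76 to 229.6 ± 2.57. Camera did not call the list (adjusted p = 0.0584, and 0.919 with an estimated correlation), but did after quantile normalization (adjusted p = 0.00512). Of 63 ribosomal protein genes 7 rose and 1 fell, with 0 adjusted over the list alone; RPL13 had 4.83 ± 0.0287 against 1.34 ± 0.447 CPM.

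SPATA18, a mitochondrial quality control gene, rose in ATRi against PARPi from 2.80 ± 0.753 to 9.42 ± 1.06 CPM (SD, n = 2 each; limma adjusted p = 0.000363), and POLH, the translesion polymerase, fell from 25.7 ± 0.997 to 16.7 ± 1.9. Against CTR siRNA SESN1 fell from 51.4 ± 1.91 to 26.8 ± 3.01 CPM and RRM2B, a ribonucleotide reductase subunit, from 9.12 ± 0.0202 to 4.66 ± 0.351. POLH shares 26.2% of its length with other listed genes.

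ATRi libraries had a narrower spread of BrdU signal per kb between genes than the other inhibitors, 1.35 against 1.53 in ATMi, while CTR siRNA had 1.33, a gap of 0.019 to ATRi that was 0.116 over genes longer than 30 kb; with no vehicle library analysed here, whether ATRi is narrowed or the others are widened is open. The pairs far apart on the main axis, RAD6i (53.1 units) and PrimPol siRNA (46.5), differed in this spread by 0.00144 and 0.084, below the gap of 0.177 (SD 0.017) between ATMi and ATRi, which lie 4.34 apart, and this argues against that axis as the whole source. With every library thinned to the smallest total the gap to ATMi was 0.178 against 0.177 before. Depth was already similar in ATMi (46228503 and 40356416 reads) and ATRi (46413162 and 43476980). An unchanged gap was therefore bound to follow, and it is no evidence on depth. After thinning the spread was 1.354 in ATRi, 1.771 in PARPi and 1.839 in RAD6i, so at equal depth ATRi stayed below those groups too. Even background DNA in ATRi cannot be told apart from other sources: a constant of 0.0467 CPM per kb would bring ATMi to the spread of ATRi, and it lies below the 1st percentile of ATRi signal (0.0585 and 0.055 in the 2 libraries), but ATMi raised by it still differed from ATRi by a residual SD of 0.297 log2 (0.337 without it, and 0.136 between the ATRi libraries), so background alone does not give the ATRi levels and its part in the spread stays open. The share of reads in listed genes was lowest in ATRi (36.7% and 37.1%), and whether background lowered it was not tested. Differences in BrdU labelling or immunoprecipitation between groups, GC content, and an effect of ATR inhibition on where DNA is made were not tested and stay open.

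The RAD6i libraries stood apart from each other. With every library thinned to the smallest total they correlated at 0.9752, below the other pairs (0.9801 to 0.9951), which argues against depth, and after length correction the SD of their log2 difference was 0.41, from 0.451, which argues against gene length as the whole cause. A PARPi sample in place of RAD6i replicate 2 could not be ruled in or out: its signal spread differed from the nearest PARPi library by 0.065 and lay nearer to RAD6i replicate 1, but with the axis of the other groups removed it correlated at 0.784 and 0.738 with the PARPi libraries and 0.575 with RAD6i replicate 1. No biological explanation was tested, since both libraries carry 1 label.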
